A study of Drosophila melanogaster with 4 samples.

How the data were processed

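Chromatin immunoprecipitation with sequencing (ChIP-seq) of histone H3 dimethylated at lysine 9 (H3K9me2) was carried out on nuclei from heads of adult Drosophila melanogaster of the wild-type Oregon-R strain. The samples comprised 2 ChIP libraries and 2 input libraries, each with a replicate number in the labels. Flies came from population cages, and formaldehyde-fixed, sonicated chromatin was precipitated, per the labels' protocols. Each input is described as the control for 1 of the region lists. The labels do not say that the replicates came from separate fly populations, so any spread between them may be technical.

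The authors deposited 3 lists of regions, 1 for each ChIP library and 1 combined list for the replicate set. The lists are on FlyBase Release 5 of the genome, per the file headers. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The region caller, its threshold and the way the replicates were combined are not given in the sources used here. Regions are classed as enriched or depleted in the deposited lists. The deposited score of a region has no stated unit. It was above 0 in all enriched regions and below 0 in all depleted ones, so it is probably a log ratio of ChIP to input, whose base is not given. Scores are the authors' own and were used to describe, rank and filter regions within a list. Scores of different lists were set side by side for named regions, for the correlation across overlapping regions and for a single test in the closing observations, and their scales may differ between lists.

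The lists carry no read counts, so the depth of each library is unknown and no interval from counting error could be given. The number and the length of called regions usually depend on depth, and part of a difference in covered length between the replicates may come from it. Read-level values of the input libraries were not used here.

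Region coordinates are given as 1-based positions. Starts at 0 were set to 1 and ends past the end of a sequence were set to its length in the file headers. This applied to 1 start and 3 ends in replicate 1, 4 ends in replicate 2, and 1 start and 6 ends in the combined list, with a largest overhang of 945 bp. Every coordinate pair in the combined list was even, against 25.2% and 25.3% of the pairs in the replicate lists, which shows a different grid of positions behind that list. The 13 sequences analysed were the 5 large arms (2L, 2R, 3L, 3R and X), chromosome 4, 6 scaffolds of mapped heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and the unplaced sequence U. The further unplaced sequence Uextra held 0 regions in the 3 lists.

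The covered share of a sequence is the length inside enriched regions divided by the sequence length in the file headers. It was computed for each replicate and given as mean ± SD (n = 2). The design has a single ChIP group, so no groups were compared, and an exact two-sided sign-flip test over the replicates cannot give p below 0.5. The centromere-proximal part of an arm was its last 2 Mb on 2L, 3L and X and its first 2 Mb on 2R and 3R, and the remainder is called distal. Proximal and distal shares were compared by an exact two-sided sign-flip permutation test over the 5 arms, whose smallest possible p is 0.0625. Such a test is over arms, not samples.

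Overlap of the replicate lists was measured in base pairs, as the Jaccard index (shared length over the length of the union), and as the share of regions touched by at least 1 bp. It was compared with 1000 circular shifts of 1 list within each sequence, one-sided, with a smallest possible p of 0.001. Scores of overlapping regions were compared by Pearson's r, without a test, and by Spearman's rho with 10000 permutations. Both are across regions, which are not independent replicates. The shift test was tested on simulated lists of 600 regions per arm. It recovered a simulated Jaccard index of 53.8% as 53.8%, which checks the computation only, since the shared regions were exact copies. Of 400 pairs of unrelated lists, with 100 shifts each, 24 had p of 0.05 or less. The simulated regions had equal length and lay at random places, so the test was not checked on clustered lists like the real ones. A change-point fit used for chromosome boundaries fell within 1 bin of the true point in 98 of 100 simulated profiles of 460 bins. Each of these profiles held a large, sharp step with independent noise, so the check does not cover arms with a weak or gradual rise.

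The regions named in the text follow a fixed rule. The lists of the replicates were intersected, and gaps of up to 1 kb were joined. The 5 longest shared regions on each large arm outside the proximal 2 Mb were ranked, and the 10 longest of these are named, with the 3 longest on chromosome 4 and the 3 longest in the proximal windows. The score given for a named region is the mean score of the regions overlapping it in a list, weighted by the overlapping length.

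A gene table of Release 6 was at hand, while the regions are on Release 5. No coordinates were converted, so no gene was assigned to a region and 15 gene lists chosen for the tissue and the mark were not tested for enrichment. Symbols of the lists were matched to the table, with 235 of 237 found, for their chromosome alone.

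The comparisons, their windows, the rule for named regions, the gene lists and the alternatives in the next sentence were fixed before the data were examined. Alternatives were the better-scoring 50% of each list, lists reduced to the covered length of the shorter list, regions under 500 bp left out, gaps up to 1 kb joined, each replicate alone, the combined list, proximal windows of 1 Mb and 5 Mb, distal arms as the reference for chromosome 4, at least 50% of a region shared, shifts within distal arms, and the largest coordinate as sequence length. Joining of gaps up to 5 kb, and tests of the X and of chromosome boundaries, were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.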

Results

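H3K9me2 was mapped by ChIP-seq in head nuclei of adult wild-type Oregon-R flies, with 2 ChIP libraries and 2 input libraries. H3K9me2 is a histone mark of heterochromatin, the condensed, repeat-rich chromatin around centromeres. Replicate 1 listed 6264 enriched regions covering 32.4 Mb, and replicate 2 listed 10907 regions covering 41.1 Mb. The authors' combined list held 10762 regions covering 47.3 Mb. Median region lengths were 2613 bp in replicate 1, 2482 bp in replicate 2 and 2383 bp in the combined list. These regions covered 23.2% of the 13 sequences of FlyBase Release 5 in replicate 1, 29.5% in replicate 2 and 33.8% in the combined list. Read depth is unknown, and no value has an interval from counting error.

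The first comparison asked where along the genome the mark lay. Enriched regions covered most of the heterochromatin scaffolds and a small part of the large chromosome arms. The 6 scaffolds together were covered over 71.2% ± 8.36 (SD, n = 2) of their length, and the 5 large arms over 19.1% ± 6.76. The share on the scaffolds was 5.38 times that on the arms in replicate 1 and 2.73 times in replicate 2. Scaffold 3LHet had the highest mean share, 76.8% ± 9.39, followed by 3RHet with 75.8% ± 8.23. The shares were 65.9% ± 7.49 on 2RHet, 65.9% ± 11.0 on YHet, 62.7% ± 4.50 on XHet and 56.7% ± 9.42 on 2LHet. Unplaced sequence U, which is rich in repeats, was covered over 68.7% ± 9.27.

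The mean share of the large arms was 23.0% ± 6.73 on 2R and 14.4% ± 6.73 on 3R. It was 21.4% ± 8.55 on X, 20.4% ± 6.01 on 3L and 17.7% ± 5.88 on 2L. These arm means differed by less than the spread between replicates or by little more than it. That spread includes a shift shared by the arms, each of which was covered more in replicate 2, so arms are better compared within a replicate. Within each replicate 3R was the lowest arm and 2R the highest, with 9.68% and 18.2% in replicate 1 and 19.2% and 27.7% in replicate 2. The top rank was not stable, since X was above 2R in the combined list (31.1% and 29.9%) and with the better-scoring 50% of regions (15.6% and 14.7%). The gap between scaffolds and arms exceeded the spread between replicates, and in each replicate the least covered scaffold, 2LHet, was covered more than every large arm. The difference was 52.0 percentage points ± 15.1 (SD, n = 2), and the exact two-sided sign-flip permutation test over the replicates gave p = 0.5, the smallest possible with n = 2. With the better-scoring 50% of each list, the mean share was 11.8% on the 5 large arms, down to 6.86% on 3R.

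The replicates differed in opposite directions on the 2 kinds of sequence. Each large arm was covered more in replicate 2, by 8.31 percentage points on 2L and up to 12.1 points on X. The large arms together had 14.3% in replicate 1 and 23.9% in replicate 2. The 6 scaffolds together had 77.1% in replicate 1 and 65.3% in replicate 2. U had 75.2% in replicate 1 and 62.1% in replicate 2.

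**Figure D1:**
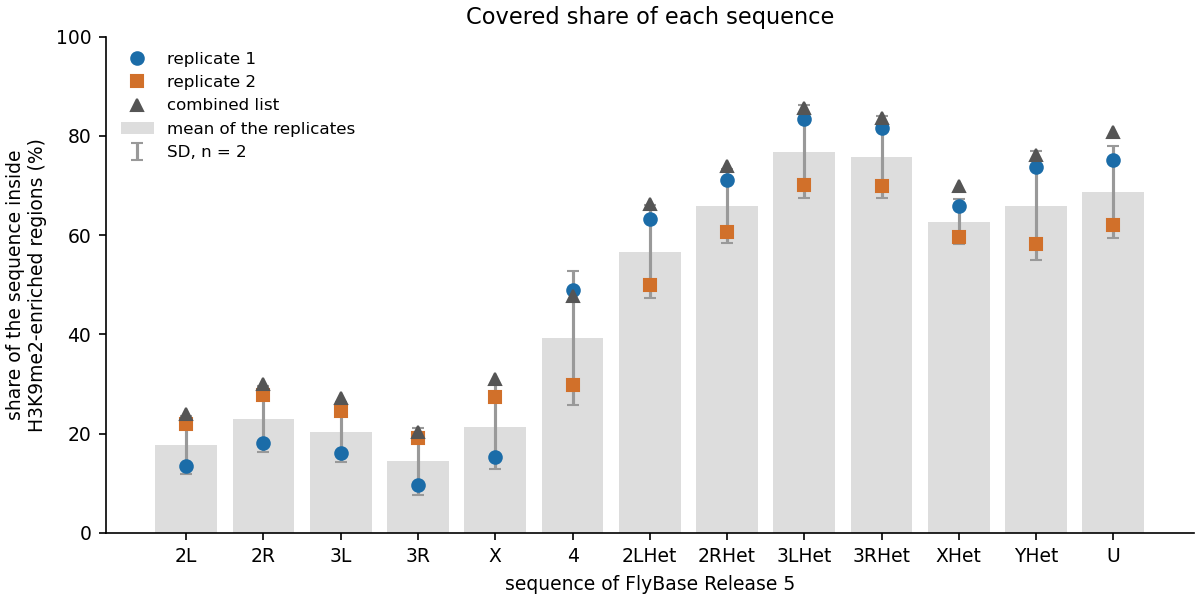
Share of each of 13 sequences (horizontal axis) inside H3K9me2-enriched regions in percent (vertical axis), with grey bars for the mean of the replicates, error bars for the SD (n = 2), and markers for replicate 1, replicate 2 and the authors' combined list. The Het scaffolds and U lie above the large arms in all 3 lists, and chromosome 4 lies between them.

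Chromosome 4, the small chromosome long known to be largely heterochromatic, was covered more than the large arms, by an amount that depended on the replicate. Its covered share was 48.9% in replicate 1 and 29.8% in replicate 2, a mean of 39.4% ± 13.5 (SD, n = 2), and 47.8% in the combined list. The ratio to the large arms was 3.41 in replicate 1 and 1.25 in replicate 2, a mean of 2.33 ± 1.53 that does not exceed 1 by more than the spread between replicates. In the Release 6 gene table this chromosome carries 80 protein-coding genes, among them ey and toy, Pax6 genes of eye development, and ci, the transcription factor of Hedgehog signalling.

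Each replicate listed 134 regions on chromosome 4, with a median length of 3258.5 bp in replicate 1 and 2085.5 bp in replicate 2. These were not all the same regions, since 46 of those of replicate 1 were not touched by replicate 2, and 19 of those of replicate 2 were not touched by replicate 1. The 3 longest shared regions on chromosome 4 were at 765177–792791 (27.6 kb), 12982–27494 (14.5 kb) and 1173259–1184369 (11.1 kb). The first of these was a single region with a score of 1.80 in replicate 1 and a pair of regions with a mean score of 1.79 in replicate 2. The direction of the ratio turned in replicate 2 under stricter lists. It was 0.92 with the better-scoring 50% of regions and 0.96 with the lists reduced to equal covered length, against 2.75 and 3.41 in replicate 1. The reduction to equal covered length removed 0 regions from replicate 1, so its 3.41 could not change. Both selections are by score, and regions on chromosome 4 had a lower median score than distal regions in replicate 2 (0.62 and 0.80), which lowers the ratio by itself. The mean covered share with the better-scoring 50% was 18.9%.

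**Figure D2:**
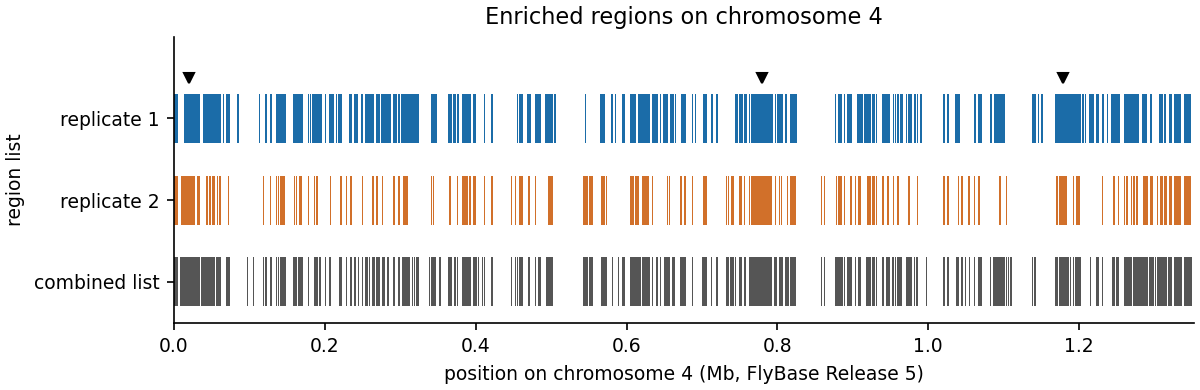
Enriched regions along chromosome 4 (horizontal axis, Mb on FlyBase Release 5) in replicate 1, replicate 2 and the authors' combined list, with triangles at the 3 longest shared regions. Regions covered 48.9% of the chromosome in replicate 1, 29.8% in replicate 2 and 47.8% in the combined list.

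The next comparison set centromere-proximal against distal sequence of the large arms. The proximal 2 Mb were covered more than the remainder of the arm on each of the 5 arms in both replicates. All 5 arms together had 45.1% proximal and 11.5% distal in replicate 1, a ratio of 3.91. In replicate 2 the shares were 43.9% and 22.1%, a ratio of 1.99. The mean ratio was 2.95 ± 1.36 (SD, n = 2), and the exact two-sided sign-flip permutation test over the 5 arms gave p = 0.063 in each replicate, the smallest it can give. The distal share was higher in replicate 2 on all 5 arms, whereas the proximal share was higher in replicate 1 on 2L, 2R and 3L and higher in replicate 2 on 3R and X. This direction depended on the window, since with 5 Mb the proximal share was higher in replicate 2 on all 5 arms, and with 1 Mb it was higher in replicate 1 on X (40.2% and 39.1%). With 5 Mb the ratio over all 5 arms was 2.44 in replicate 1 and 1.53 in replicate 2.

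Within the arm sequences, 3L, 2R and 2L carried the proximal excess, and 3R and X had much less of it. The windows leave out the separate Het scaffolds, where 3RHet had a mean share of 75.8% and XHet 62.7%. How far each arm sequence reaches into heterochromatin was not examined. On 3L the proximal share was 68.9% in replicate 1 and 61.1% in replicate 2, against 11.4% and 21.4% in the distal part. On 2R it was 64.3% and 58.1%, against 13.4% and 24.5%. On 2L it was 49.3% and 45.8%, against 10.2% and 19.6%. On X it was 28.3% and 31.1%, against 14.1% and 27.1%. On 3R it was 14.5% and 23.6%, against 9.31% and 18.9%. The 3 longest shared regions of the proximal windows were on 2L at 22576513–22640916 (64.4 kb) and 22507030–22566666 (59.6 kb), and on 2R at 1434508–1488832 (54.3 kb). Between 97.4% and 100% of the length of each was covered in either replicate, which the rule for shared regions largely fixes. With the better-scoring 50% of regions, the ratio over all 5 arms rose to 6.49 in replicate 1 and 2.69 in replicate 2, a mean of 4.59, where proximal regions had higher scores than distal ones.

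**Figure D3:**
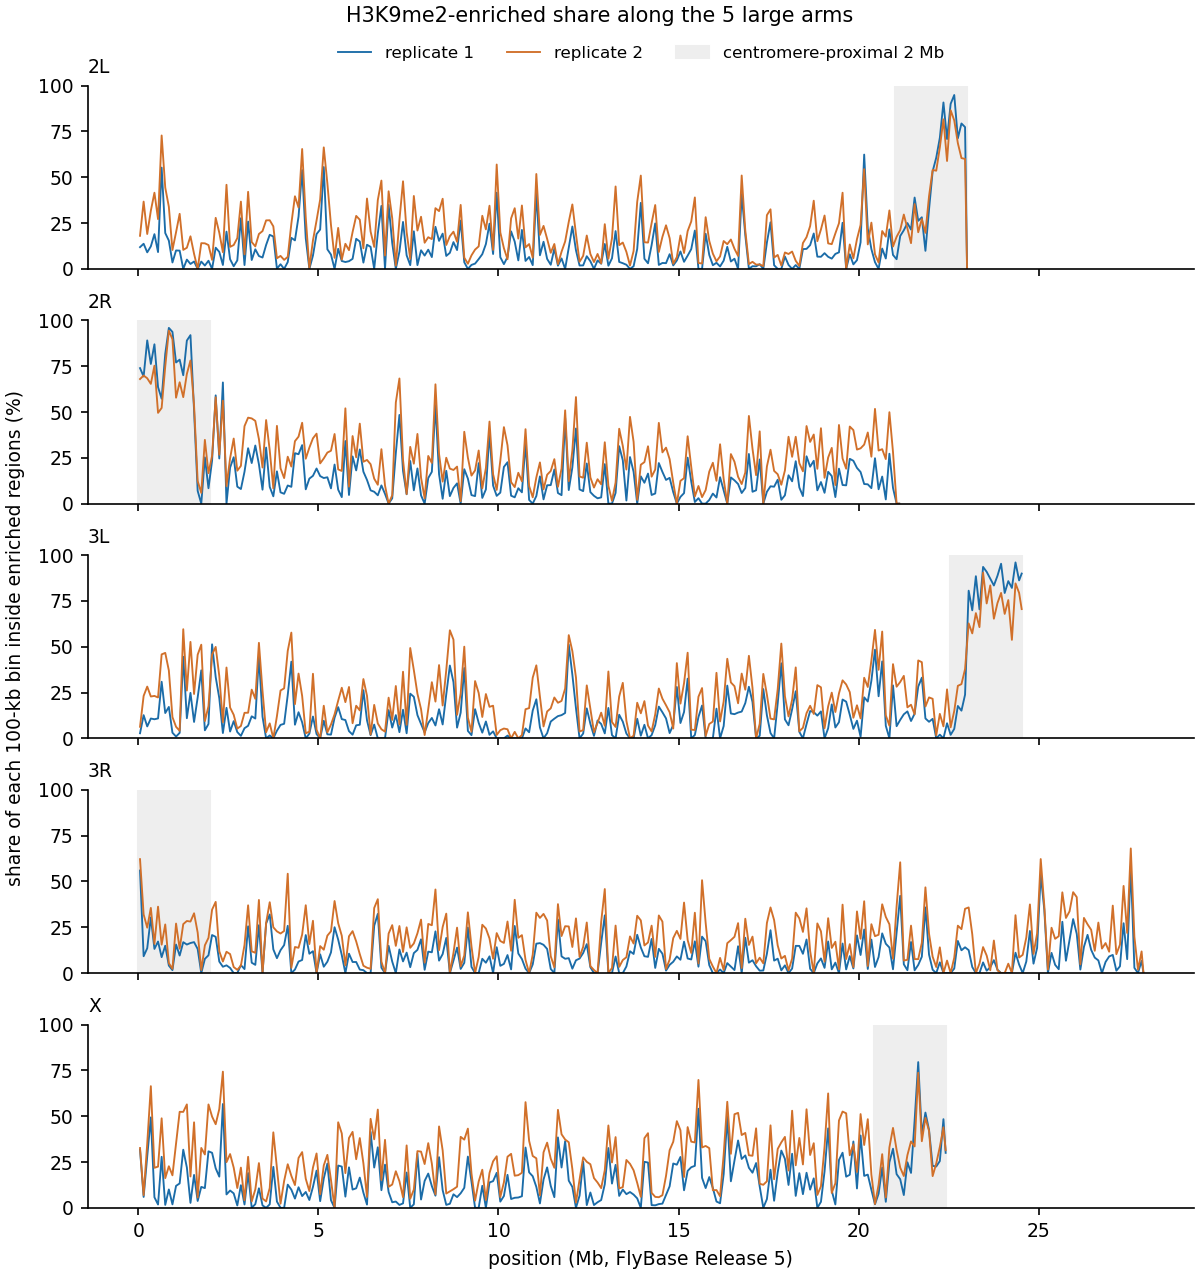
Share of each 100-kb bin inside enriched regions (vertical axes, percent) along the 5 large arms (horizontal axis, Mb on FlyBase Release 5), with a line for each replicate and the centromere-proximal 2 Mb in grey. Shares rise within the grey windows of 2L, 2R and 3L, and the line of replicate 2 lies above that of replicate 1 in at least 92.3% of the distal bins of every arm.

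Regions on the Het scaffolds, on U and in the proximal windows had higher median lengths and scores than regions on the distal arms, in each replicate. Regions on chromosome 4 had a lower median score than distal regions in each replicate, and a higher median length in replicate 1 only. The median length in replicate 1 was 7681 bp on the Het scaffolds and 2189.5 bp on the distal arms. In replicate 2 the medians were 3907 bp and 2271 bp. Regions of at least 10 kb made up 42.2% of scaffold regions and 2.24% of distal regions in replicate 1, and 19.6% and 2.57% in replicate 2. The median score within replicate 1 was 2.03 on the scaffolds, 2.49 on U, 1.01 in the proximal windows, 0.80 on the distal arms and 0.73 on chromosome 4. Within replicate 2 the medians were 1.56, 2.03, 0.99, 0.80 and 0.62 in the same order. Longer regions had higher scores in both lists, with Spearman's rho of 0.71 in replicate 1 and 0.73 in replicate 2 across regions.

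**Figure D4:**
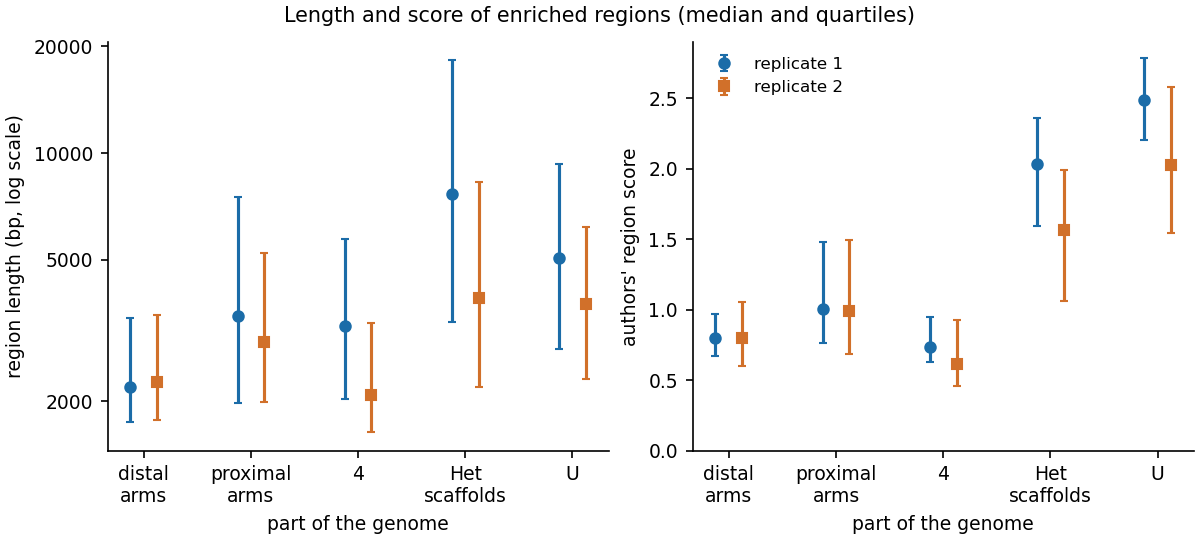
Median (markers) and quartiles (bars) of region length in bp on a log axis (left) and of the authors' region score (right) in 5 parts of the genome for replicate 1 and replicate 2. Regions on the Het scaffolds and U are longer and have higher scores than those on the distal arms in both replicates.

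The positions of the enriched regions were compared between the replicates. The lists shared 27.7 Mb, which was 85.4% of the length in replicate 1 and 67.4% of that in replicate 2. The Jaccard index was 60.4%, against a mean of 23.0% and a maximum of 25.4% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest possible). Of the regions of replicate 1, 93.6% were overlapped by replicate 2, against 52.1% under shifts. Of the regions of replicate 2, 60.9% were overlapped by replicate 1, against 37.9%. On the distal arms alone the Jaccard index was 48.0% against 8.38% under shifts, on chromosome 4 48.0% against 22.7%, and on the Het scaffolds 80.0% against 55.2%. On the Het scaffolds the share of replicate 1 regions touched by replicate 2, 89.0%, did not differ detectably from the 87.6% under shifts (one-sided permutation p = 0.208). With at least 50% of the region shared it was 82.2% against 71.1%, and 98.1% of replicate 2 regions were touched by replicate 1 against 87.9% (permutation p = 0.001 each, the smallest possible).

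Regions of replicate 2 that were missing from replicate 1 lay mostly on the distal arms and had lower scores than the others. There were 4269 of them, 4014 on the distal arms, with a median score of 0.65 against 1.17 for the overlapped ones. The pattern was different on the Het scaffolds, where 18 such regions had a median score of 2.80 against 1.55. Regions of replicate 1 missing from replicate 2 numbered 404, of which 121 lay on the distal arms. The 404 had a median score of 0.90 against 0.91 for the overlapped ones, which mixes parts with different score levels. Missing regions scored lower on the distal arms (0.72 against 0.80), the Het scaffolds (1.63 against 2.06) and chromosome 4 (0.63 against 0.86). Of the highest score quartile of replicate 1, over all parts, 90.7% of regions were overlapped by replicate 2, and of the lowest, 91.4%. Of the lowest score quartile of replicate 2, 24.0% of regions were overlapped by replicate 1, and of the highest, 97.3%. Over the 5860 regions of replicate 1 overlapped by replicate 2, Spearman's rho of the scores was 0.81 (permutation p = 0.0001, the smallest possible). Pearson's r was 0.84, without a test. Within parts of the genome rho was lower or equal, at 0.81 in the proximal windows, 0.71 on the distal arms, 0.66 on chromosome 4, 0.62 on the Het scaffolds and 0.57 on U. All of these coefficients are across regions, which are not independent replicates. The covered shares of distal 100-kb bins had Pearson's r between 0.87 on X and 0.91 on 3L, also across bins.

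The shared lists held 3459 regions on the distal arms, of which 155 were at least 10 kb long. The longest was on 3R at 25077771–25136335 (58.6 kb), covered over 96.0% in replicate 1 by 7 regions and in full in replicate 2 by a single region. It was followed by 2R 8240877–8286912 (46.0 kb), 3L 11938582–11983191 (44.6 kb), 2L 16763404–16803634 (40.2 kb) and 2L 4478992–4513883 (34.9 kb). The last of these was a single region in each list, with a score of 1.38 in replicate 1 and 1.85 in replicate 2. The X had regions at 15553590–15585621 (32.0 kb) and 20068545–20098864 (30.3 kb). The other named regions were on 2R at 11844387–11875760 (31.4 kb), 7218302–7244386 (26.1 kb) and 10758871–10784361 (25.5 kb). Their mean scores in replicate 1 lay between 1.11 and 1.56, above the distal median of 0.80. These regions were chosen by length, and longer regions had higher scores, so this follows at least in part from the choice. Which genes these regions contain was not analysed here.

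The combined list held nearly all of what the replicates shared and most of what only 1 of them listed. It contained 99.996% of the shared length, 97.8% of the length of replicate 1 and 97.4% of that of replicate 2. Of the length listed in replicate 1 alone it held 84.6%, and of that in replicate 2 alone, 92.1%. The share of the combined list inside the union of the replicates was 93.2%, as a description only, since the list was made for the same pair of libraries. The remaining 6.79%, or 3.21 Mb, lay outside both replicate lists. This part included 1233 regions that overlapped neither replicate, with a median length of 1213 bp and a median score of 0.47 against 0.66 for the others. On chromosome 4 it kept 58.9% of the length listed in replicate 1 alone and 98.0% of that in replicate 2 alone.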

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

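The test of where depleted regions lay was chosen only after these regions were seen. The comparisons above use enriched regions only, and the combined list also held 7 regions classed as depleted, on 2L, 3L and 3R, with scores from -0.105 to -0.000736. Each of the 7 had more than 50% of its length inside enriched regions of 1 replicate list and 0 bp inside those of the other. Over 10000 random placements 1.65 of the 7 were expected inside a replicate's enriched regions (one-sided permutation p = 0.0001, the smallest possible). Random placement is not a fair reference here, since the combined list was made for the same pair of libraries. No conclusion is drawn from this p. Replicate 2 listed a single depleted region, on 2RHet at 1375063–1376654, and all of its 1592 bp lay inside enriched regions of replicate 1 and of the combined list.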

How the results depend on the processing

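Joining of gaps up to 5 kb, and the alternatives for the X and for chromosome boundaries, were chosen only after the results were seen. Averaged over the replicates, the chromosome 4 ratio and the proximal to distal ratio stayed above 1 under the alternatives, and the Het scaffolds stayed above the large arms. The order of 2R and X turned. Their mean shares were 23.0% and 21.4%, but 14.7% and 15.6% with the better-scoring 50% of regions and 19.17% and 19.22% at equal covered length. The ratio of chromosome 4 to the large arms in replicate 2 alone reversed, from 1.25 to 0.92 with the better-scoring 50% of regions and to 0.96 with lists reduced to equal covered length. Both select by score, and chromosome 4 regions of replicate 2 had a lower median score than distal regions (0.62 and 0.80), so the selection lowers the ratio by itself. With the better-scoring 50%, the mean share of the large arms fell to 11.8% and the proximal to distal ratio rose to 4.59; the selection removes regions by construction, and proximal regions had higher median scores than distal ones (1.01 and 0.80 in replicate 1, 0.99 and 0.80 in replicate 2), so it raises the ratio by itself. Proximal windows of 1 Mb and 5 Mb gave mean ratios of 3.65 and 1.98; with 5 Mb the ratio was 2.44 in replicate 1 and 1.53 in replicate 2. The combined list gave 26.2% on the large arms, and joining gaps up to 5 kb gave 80.5% on the Het scaffolds, where joining itself adds covered length. Leaving out each replicate in turn gave 14.3% to 23.9% on the large arms, 65.3% to 77.1% on the Het scaffolds, a chromosome 4 ratio of 1.25 to 3.41 and a proximal ratio of 1.99 to 3.91. The Jaccard index ranged from 48.0% to 64.8% and Spearman's rho of the scores over the whole genome from 0.78 to 0.81, each above its permutations. Leaving out regions under 500 bp removed 0 regions and tests nothing. Overlap and score correlations need both replicates and have no value without 1 of them. The alternatives for the gene lists were not run, since no annotation of Release 5 was used here. No paired analysis was possible because no region list of the input libraries was used here, so that ChIP and input could not be fitted together. Depth is unknown, and a region missing from a list may have been below detection in that library. At equal covered length replicate 2 kept 6498 of 10907 regions.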

Other observations

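The tests of the replicate difference, of the X score offset and of the chromosome boundaries were chosen only after the results were seen; the other tests of the X and that of chromosome 4 were set before their own results were seen, on patterns noticed in the data. Coverage rose towards the centromere on 2L, 2R and 3L. A change-point fit in 50-kb bins, which places a single step whether a rise is sharp or gradual, placed it at 22.05 Mb on 2L and 23 Mb on 3L in both replicates, and at 1.55 Mb on 2R in replicate 1 and 1.6 Mb in replicate 2, so that the replicates differed by at most 50 kb on these arms. In replicate 1 mean coverage on 3L was 11.5% before the fitted point and 85.2% after it, and in replicate 2 21.4% and 71.8%. On 3R the fit also gave the same point, 0.1 Mb, in both replicates, with mean coverage of 56.0% before and 9.52% after it in replicate 1, and 62.2% and 19.05% in replicate 2. That point rests on the first 100 kb of the arm, and the points were 24300 kb apart in 100-kb bins. On X the fitted points differed, at 21.5 Mb in replicate 1 and 14.7 Mb in replicate 2. In 50-kb bins the step took up little of the variance between bins on 3R (shares of 0.052 in replicate 1 and 0.024 in replicate 2) and on X (0.12 and 0.039). On 2L, 2R and 3L the share was at least 0.25 in each replicate. The terminal 100 kb at the telomeric end of the X were covered over 31.7% in replicate 1 and 32.6% in replicate 2, against 14.1% and 27.1% of its distal part. The same ends had 11.9% and 18.1% on 2L, 2.79% and 6.32% on 3L, 6.74% and 11.8% on 3R, and no enriched region in either replicate on 2R.

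The distal X was covered more than the distal autosomal arms, pooled or each alone, in both replicates. The closest was distal 2R, with 13.4% against 14.1% on the distal X in replicate 1 and 24.5% against 27.1% in replicate 2. The lowest was distal 3R, with 9.31% and 18.9%. The block test pools the autosomal arms and does not account for differences between arms. In 1-Mb blocks, 20 on X and 87 on autosomes, the ratio was 1.27 in replicate 1 (95% bootstrap interval 1.06 to 1.49, permutation p = 0.0060, Benjamini-Hochberg 0.0065 over 8 tests) and 1.28 in replicate 2 (1.13 to 1.45, p = 0.00011, adjusted 0.00022). Blocks are not samples. The 8 tests are settings of this same comparison in both replicates. Their adjustment does not cover the choice of the X after the arm values were seen. Pericentric sequence between 2 Mb and 5 Mb is argued against as the sole cause by ratios of 1.29 and 1.28 without the proximal 5 Mb. A rise reaching beyond 5 Mb was not tested and stays open, since the fitted point on X in replicate 2 was at 14.7 Mb. The ratios of 1.82 and 1.75 with the better-scoring 50% do not decide on low-scoring regions, since X regions scored higher and a selection by score raises the ratio by itself. An X-wide difference between the ChIP and input libraries may be the cause: X regions scored above autosomal regions of equal length by a median of 0.17 in replicate 1 and 0.19 in replicate 2, with 0.15 to 0.18 and 0.17 to 0.20 over length quartiles, while the same difference for each autosomal arm lay between -0.020 and 0.015. A true excess of H3K9me2 along the X predicts the same values, so it stays open, and no biological explanation was tested, since the design has no groups by sex or dosage.

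Replicate 2 listed more of the arms and less of the heterochromatin than replicate 1. A more permissive threshold alone would add length everywhere and is argued against by the 8 of 8 heterochromatic sequences (6 scaffolds, U and 4) covered less in replicate 2, while greater depth stays open, since read totals were not used here. Gaps of up to 1 kb are argued against as the main cause, since joining them closed 7.08% of the difference on the Het scaffolds, but joining up to 5 kb closed 50.1%, so breaks of that size stay open. Joining adds covered length to either list, here to 83.5% in replicate 1 and 77.6% in replicate 2. Part of the closing with 5 kb may therefore come from joining itself. A smaller score difference between heterochromatin and arms in replicate 2 stays open: over overlapping regions the score change on the scaffolds was -0.45 relative to the distal arms (95% bootstrap interval -0.49 to -0.41), but the scale of the scores is not given and may differ between lists. That interval resamples regions, which are not independent replicates. No biological explanation was tested, since both libraries belong to the same group.

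The covered share of chromosome 4 was 3.41 times that of the large arms in replicate 1 but 1.25 times in replicate 2. Its regions had lower median scores than distal regions. The median difference was -0.068 in replicate 1, with a 95% bootstrap interval of -0.095 to 0.00099 that includes 0, and -0.18 in replicate 2 (-0.21 to -0.094). Region length is argued against as the cause, since against distal regions of equal length the difference was -0.13 (-0.16 to -0.11) in replicate 1 and -0.094 (-0.13 to -0.058) in replicate 2. Of the chromosome 4 regions, 79.1% and 70.9% scored below their length-matched distal regions. The intervals resample neighbouring regions within a library, which are not independent replicates, so they do not measure the spread between samples. Other explanations were not tested.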
